A study of Homo sapiens with 4 samples.

How the data were processed

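The series holds 4 libraries of the human acute myeloid leukemia line MOLM13, of which 2 carry the label negative control sgRNA and 2 the label NMNAT1 sgRNA. Per the labels' protocols, RNA was taken from sorted cells, amplified as full-length cDNA with a SMART-Seq2 kit and fragmented and barcoded with a Nextera XT kit. That kind of library has no molecular identifiers and no strand information, so copies made in amplification count as reads, and reads of overlapping or antisense genes cannot be told from each other. The submitters' processing notes name the tools STAR, DESeq2 and HOMER and the genome builds hg38 and hg19, with no roles; versions are not given in the sources used here. The authors deposited 1 table of FPKM per gene and library with gene IDs and symbols. The columns were assigned to the groups by their names.

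The deposited FPKM were not plain per-million values. Each gene's values across the libraries were ratios of whole numbers, from which whole reads could be recovered for all 15272 listed genes to within rounding of the file. The recovered divisors of the libraries equalled median-of-ratios size factors over the 9662 genes above 0 in every library, so between-library scaling by size factors is already in the values. Of 3008 genes with over 1000 recovered reads, 96.4% gave a whole gene length (tolerance 1e-06 bp), and 67.6% gave the length of all exons of the gene in GENCODE v29. In simulated data with 1943 genes of 100 or more reads, the recovery was exact for 98.9%. Reads recovered for genes with few reads can be too low by a common factor. The reads were used for depth, for CPM and for alternatives, not for the main test. The recovered totals were 13850183 and 11268759 for the control libraries and 10711313 and 12863840 for the libraries labelled NMNAT1 sgRNA. The spread between replicates exceeded read-counting error, with a chi-square per degree of freedom of 43.8 over 7238 genes in the control group and 18.3 over 9350 genes in the other, which does not tell technical from biological spread. Each library was counted as 1 replicate.

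The test planned for counts was not used because the table held FPKM, and the test planned for that case took its place. Values were set to log2(FPKM + 1), genes with an FPKM of at least 1 in at least 2 libraries were kept, and limma 3.58.1 in R 4.3.3 was fitted with an intensity-dependent prior (limma-trend) and no covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes called log2 are on the log2(FPKM + 1) scale, which understates the change of low genes, and fold values in words are ratios of mean FPKM. Errors are the SD of the 2 libraries of a group, or limma's SE. In simulated reads with the real means and 200 genes changed, none of them by a trend, limma recovered 8% of the 1.5-fold, 60% of the 2-fold and 90% of the 4-fold and of the 8-fold changes among 5371 tested genes, with 16 false calls. With a simulated GC trend between the groups there were 2964 false calls among 5916 tested genes, and 112 among 5844 after the correction described next. Beside at most 200 true calls, 112 false ones are a larger share than the threshold of 0.05 aims at. The simulated trend was linear and the same in both libraries of a group, with no length trend, so the real data may be harder to correct. All simulated genes shared 1 dispersion (spread beyond counting error), 0.026, in both groups. The simulated false calls thus do not carry over to genes with uneven replicates.

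Before the data were examined, 24 gene lists were fixed from general knowledge: p53 targets, NAD synthesis and NAD consumers, BCL2 family, G1/S, G2/M, DNA repair, interferon, ATF4, unfolded protein response, myeloid differentiation, MLL targets, ribosome biogenesis, ribosomal proteins, oxidative phosphorylation (nuclear and mitochondrial), glycolysis, cholesterol, NF-kB, immediate early and heat shock genes, histones, and markers of lymphocytes, of erythroid and megakaryocytic cells, and of epithelial, fibroblast and packaging cells. Symbols were matched to the table, 17 of them through older or newer names. The 20 lists with at least 5 tested members were tested with camera in limma, on the same values, at a preset inter-gene correlation of 0.01, adjusted over the lists. With an estimated correlation camera called none of them. That form rests on the 2 residual degrees of freedom of the fit and can hardly call a list. For nuclear oxidative phosphorylation genes the estimate, 8.01e-04, was below the preset 0.01, yet camera's unadjusted p went from 6.46e-05 to 0.0384. A high adjusted p with an estimated correlation thus does not decide about a list. Named genes followed a rule also fixed before: NMNAT1; the 10 largest increases and 10 largest decreases in log2 fold change among called genes with a mean of at least 5 CPM and no overlap of the groups; up to 3 called members of each list (8 for p53 targets) by adjusted p, or up to 2 values where none passed; and CD38, SIRT6, SIRT7, PARP1, NAMPT, NMNAT2, NMNAT3, CDKN1A, MDM2, BAX and BBC3. The rule also named 2 genes that are not reported here.

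GC content and length were those of the longest transcript per symbol, coding transcripts first, in GENCODE v29 on GRCh38, which gave values for 5707 of the 5779 tested genes, and coordinates come from the same annotation. For the correction, the deviation of each library from the gene mean was fitted with natural splines of GC content and of log2 length (4 degrees of freedom each) and the fitted part was subtracted before the same limma fit. Alternatives listed before the data were examined were a pseudocount of 0.1, no filter, a filter at 5 CPM, total reads as the scale, the replicate number as a block, leaving out each library, a 2-fold minimum, a threshold of 0.01, camera with an estimated correlation, and fry. The correction, with and without an interaction of GC content and length, quantile normalization, median centring, limma-voom on the recovered reads and a minimum of 10 FPKM were added after the data were examined, as were 6 further gene lists (STAT5 targets, ERK response, hypoxia, actin and SRF targets, late neutrophil genes, other short-lived mRNAs). The form with an interaction was computed first, and the additive form is the one used where no form is named. Mitochondrially encoded mRNAs were not analysed here. Fits that leave out a library give a group with 1 library, which is then assumed to vary like the other group. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the tables and plots.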

Results

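RNA was measured in MOLM13, a human acute myeloid leukemia cell line that carries a KMT2A (MLL) fusion and an internal tandem duplication of FLT3. Cas9-expressing MOLM13 cells received a lentiviral single guide RNA (sgRNA) against NMNAT1, the nuclear enzyme that makes NAD from nicotinamide mononucleotide, or a negative control sgRNA. Cells were sorted 4 days after transduction, and 2 libraries per group were made from polyadenylated RNA as amplified full-length cDNA. The comparison asks how the transcriptome of these leukemia cells differs after NMNAT1 is targeted. The values are FPKM, to which the authors' size factors had already been applied. Whole reads recovered from them came to 13850183 and 11268759 in the control libraries and to 10711313 and 12863840 in the libraries labelled NMNAT1 sgRNA. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

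The target gene came first. NMNAT1 (gene ID 64802, chromosome 1, 9943428 to 9985501, plus strand, GRCh38 with GENCODE v29) was barely detected, and its RNA was higher, not lower, in the libraries labelled NMNAT1 sgRNA. NMNAT1 stood at 0.156 and 0.0424 FPKM (9 and 2 reads) in the control libraries and at 0.815 and 0.452 FPKM (57 and 35 reads) in the libraries labelled NMNAT1 sgRNA. The group means were 0.0993 ± 0.0805 FPKM and 0.634 ± 0.257 FPKM (SD, n = 2 each), a difference of 0.56 on the log2(FPKM + 1) scale. NMNAT1 lay below the minimum level for testing. With all 15272 listed genes tested, limma gave it an adjusted p of 0.0517, which was 0.0369 with the replicate number as a block and 0.0316 after the GC and length correction described below. A Cas9 cut need not lower the level of an mRNA, so this value does not check the labels, and the groups are named below by their labels. The annotation names 5 NMNAT1 pseudogenes, and reads from those copies are not separated here.

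Most tested genes differed between the groups. Of 5779 genes with an FPKM of at least 1 in 2 libraries, 2149 were higher and 2288 were lower in the libraries labelled NMNAT1 sgRNA (limma, adjusted p under 0.05). PIM1, a serine/threonine kinase induced by STAT5, fell from 854 ± 29.2 FPKM in control libraries to 82.4 ± 3.88 FPKM (SD, n = 2 each), which is 10.4-fold lower. DDIT4, an mTORC1 inhibitor induced by stress, was 9.38-fold lower, and ADM, the gene of the vasodilator peptide adrenomedullin, was 11.6-fold lower. Among the genes that rose, the myeloid microRNA gene MIR223 went from 2.17 ± 0.314 to 82.7 ± 2.89 FPKM. Its control values rest on 3 and 2 reads, against 129 and 136 in the others. The calcium-binding protein gene S100P went from 0.932 ± 0.135 to 37.3 ± 1.33 FPKM, and SLPI, a secreted protease inhibitor of neutrophils, was 20.6-fold higher. When control sgRNA or NMNAT1 sgRNA libraries were left out one at a time, only the count of lower genes without NMNAT1 sgRNA replicate 1 moved by over 1.5 times, to 1409. With total recovered reads in place of the authors' size factors, the median log2 fold change shifted up by 0.46, and 2605 genes were called higher and 1300 lower, so that the higher share of calls went from 48.4% to 66.7%.

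The 10 largest increases that met the naming rule were MIR223, SNRPE, S100P, PDZD11, PINLYP, SLPI, NUDT2, NPM1, CCT8 and ORM1. Their log2 fold changes ran from 3.76 for ORM1, an acute-phase plasma protein, to 4.73 for MIR223, with limma adjusted p between 6.16e-06 and 9.13e-06. Control values rest on 5 and 8 reads for PINLYP and on 5 and 6 for ORM1. After the GC and length correction described below, the log2 fold change of SNRPE went from 4.35 to 2.75. NPM1, a nucleolar chaperone, was listed at 0.939 and 0.615 FPKM in control libraries against 28.9 and 24.5 FPKM. NPM1, with 45 named pseudogenes, SNRPE, with 9, and CCT8, with 1, may share reads with copies and are uncertain, as is ORM1, whose neighbour ORM2 is nearly identical; read assignment was not examined. MIR223 (chromosome X, 66018870 to 66018979) lies within an exon of a longer host transcript, AL034397.3, and PDZD11 overlaps exons of KIF4A. MIR223 reads in these libraries of polyadenylated RNA may come from the host transcript, and the mature microRNA was not measured. Among the 10 largest decreases were PIM1, DDIT4, EGR1, ADM, TNFSF9, ETS2, SNX20, RAC1 and IER2. Their log2 fold changes ran from −2.58 for the immediate early gene IER2 to −3.36 for PIM1 (chromosome 6, 37170203 to 37175426). EGR1, an immediate early transcription factor, had 28.8 and 7.95 FPKM in control libraries and 0.852 and 0.915 FPKM in the others. TNFSF9, a cytokine of the tumor necrosis factor family, was uneven in the controls, at 17.7 and 97.6 FPKM. The TNFSF9 call was lost without either NMNAT1 sgRNA library (limma adjusted p 0.0738 and 0.105), and that of RAC1, a small GTPase with 9 named pseudogenes, without NMNAT1 sgRNA replicate 2 (adjusted p 0.0554).

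**Figure D1:**
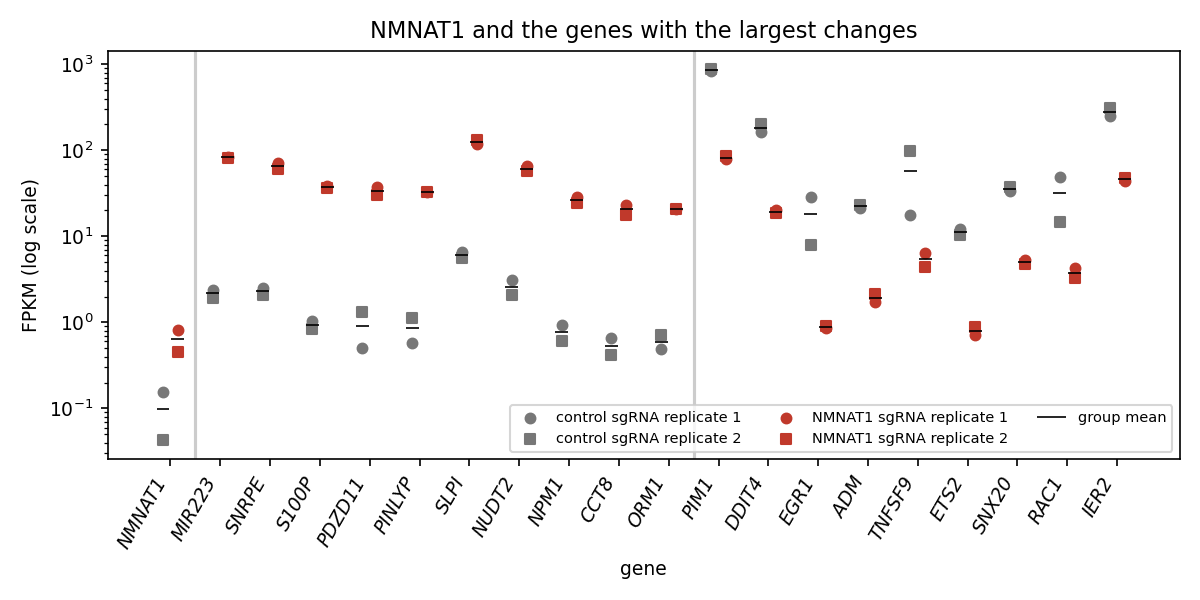
FPKM on a log axis for NMNAT1 and for the 10 largest increases and 9 of the 10 largest decreases, with one point per library (grey control sgRNA, red NMNAT1 sgRNA, circle replicate 1, square replicate 2) and a bar at each group mean. Both libraries labelled NMNAT1 sgRNA lie above both controls for NMNAT1, and the rule that named the other genes asked for such a separation, with PIM1 at 833 and 874 FPKM against 79.7 and 85.1 FPKM.

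The libraries of the groups also differed in how many genes they held and in base composition. Control libraries listed 11893 and 11099 genes above 0, and libraries labelled NMNAT1 sgRNA listed 13413 and 13813. At the depth of the shallowest library the expected numbers were 11527 and 11031 against 13413 and 13618. FTL, the ferritin light chain, took 13.6% and 12.4% of the reads in control libraries and 7.68% and 8.50% in the others, and the 100 most abundant genes took 61.1% and 60.3% against 47.0% and 48.6%. Genes with GC-rich transcripts were lower, and genes with AT-rich transcripts higher, in the libraries labelled NMNAT1 sgRNA. Among listed genes with a GC value, those under 40% GC had medians of 0.0262 and 0.0179 FPKM in control libraries, against 0.142 and 0.123. Those over 60% GC had 1.44 and 1.25 FPKM in control libraries, against 0.631 and 0.812. Whether low control values of AT-rich genes reflect the cells or the libraries was not tested. In the eighth of tested genes with the lowest GC content, 468 of 714 were higher, with a median log2 fold change of 1.16. In the eighth with the highest GC content, 499 of 714 were lower, with a median of −0.87. Across genes, which are not independent replicates, Spearman's rho with log2 fold change was −0.43 for GC content and −0.23 for transcript length. A trend with GC content also ran within the NMNAT1 sgRNA group, where rho with the difference of replicate 1 minus replicate 2 was −0.61, against −0.09 in the control group. After each library's trend with GC content and length was removed, limma called 2152 genes higher and 1718 lower of 5707. Of the 3251 genes called both before and after, 97 had the opposite direction. Values named below as corrected come from that fit, which was chosen after the data were examined. Of 91 called named genes, 23 had a corrected log2 fold change smaller by over 1.5 times or, for DOT1L and BBC3, of the opposite sign.

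**Figure D2:**
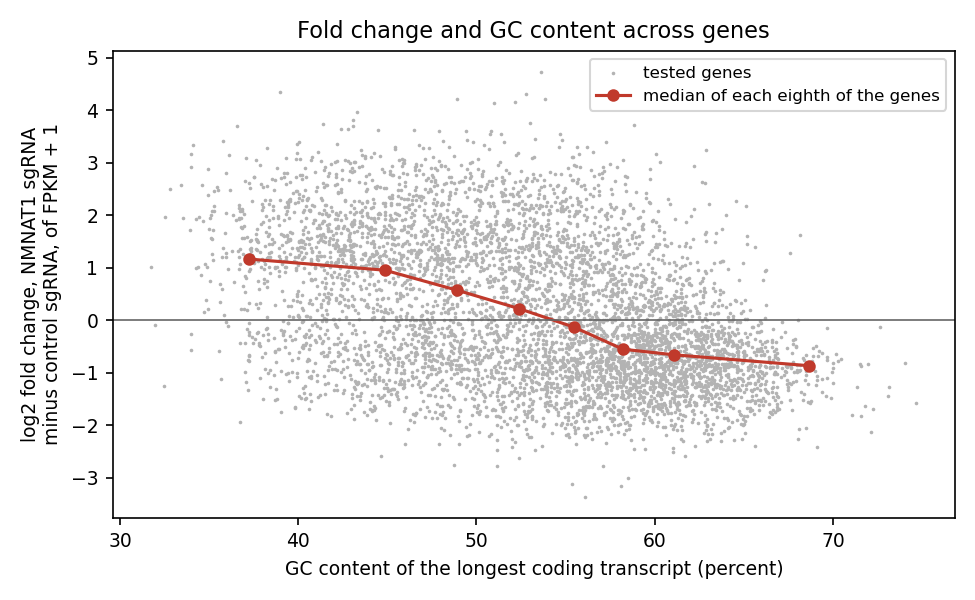
Log2 fold change of FPKM + 1 (NMNAT1 sgRNA minus control sgRNA, vertical axis) against the GC content in percent of the longest transcript (horizontal axis), one grey point per tested gene, with red points at the median of each eighth of the genes. The medians go from 1.16 in the lowest eighth to −0.87 in the highest.

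Genes of the p53 target list, which act in cell cycle arrest, DNA repair and apoptosis, moved in both directions. Of 28 tested members of the p53 list, 7 were higher, 13 were lower and 8 did not pass. DDB2, a damage recognition factor of nucleotide excision repair, rose from 3.59 ± 0.0657 to 24.8 ± 1.41 FPKM (SD, n = 2 each). TRIAP1, CCNG1 and RPS27L rose as well, by 2.93, 2.56 and 2.06 on the log2 scale (1.74, 1.65 and 1.92 corrected). Control values rest on 20 and 7 reads for TRIAP1 and on 9 and 4 for CCNG1. PLTP, which overlaps exons of CTSA, rose by 1.32 (1.86 corrected). CDKN1A, the cell cycle inhibitor p21, fell from 198 ± 8.44 to 97.8 ± 10.8 FPKM (log2 fold change −1.01 ± 0.18 SE, limma adjusted p = 0.000687), and SESN2 and the phosphatase gene PPM1D fell too, with corrected values of −0.58 for SESN2 and −0.65 for CDKN1A. MDM2, a ubiquitin ligase gene of the list, was listed at 0.159 and 0.00807 FPKM in controls and at 0.234 and 0.143 FPKM in the others, below the minimum for testing. BAX, a pore-forming apoptosis effector, had a log2 fold change of 0.23 ± 0.27 (limma adjusted p = 0.441) and passed at 0.62 without control sgRNA replicate 1 (adjusted p 0.0220). BBC3 (PUMA) had −0.76 ± 0.31 (adjusted p = 0.0465), a call lost without control sgRNA replicate 1 (adjusted p 0.406), NMNAT1 sgRNA replicate 1 (0.286) or NMNAT1 sgRNA replicate 2 (0.225), and its value was 0.48 when corrected. The list's median log2 fold change was −0.24 and its mean 0.04, with camera adjusted p = 0.782. With total-read scaling 12 members were called higher and 5 lower, and the median was 0.30. It was 0.11 at 5 CPM, 0.02 without a filter (7 higher, 6 lower) and 0.31 with at least 10 FPKM (4 higher, 3 lower). Corrected, 9 were higher and 9 lower. Without NMNAT1 sgRNA replicate 1 or 2, the 13 lower members became 4 or 5, and without replicate 1 the median was −0.15.

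Enzymes of NAD metabolism went both ways. Of 8 tested genes of NAD synthesis and salvage, 3 were higher, 3 were lower and 2 did not pass. PNP, which splits nicotinamide riboside among other nucleosides, was 13.2-fold higher (1.57 ± 0.155 to 20.7 ± 4.27 FPKM). AFMID and HAAO, of the route from tryptophan, rose by 2.20 and 1.47 on the log2 scale. NAMPT, the rate-limiting enzyme of NAD salvage, stood at 0.00969 and 0.0237 FPKM in controls and at 0.0878 and 0.123 FPKM in the others, too low to test. These NAMPT values rest on 1 and 2 reads against 11 and 17. NAMPT has 3 named pseudogenes, overlaps exons of AC007032.1 and has a transcript of 36.3% GC, so its level is uncertain. NMNAT2 and NMNAT3, the other enzymes of the NMNAT family, were at or below 0.0728 FPKM in every library. Among 12 tested sirtuins, PARPs and other NAD consumers, 3 were higher, 6 were lower and 3 did not pass. SIRT2, which overlaps exons of NFKBIB, was 2.70-fold higher. SIRT4 rose by 1.42 on the log2 scale (0.66 corrected) from 0 and 0.0876 FPKM in controls, and CD38, a NAD glycohydrolase, rose by 0.80. PARP16 fell by 1.73 and PARP1, the main DNA damage PARP, fell by 0.95, a call of PARP1 lost without either NMNAT1 sgRNA library (limma adjusted p 0.0780 and 0.0720). SIRT6, with a transcript of 64.9% GC, fell by 1.11 (adjusted p = 0.000650) and by 0.36 when corrected (adjusted p = 0.0765). SIRT7 had a log2 fold change of −0.02 ± 0.22 (adjusted p = 0.927). Camera called neither list (adjusted p 0.759 and 0.496). The median of the synthesis list was 0.13. It was 0.57 when corrected (4 higher, 2 lower), 0.53 with total-read scaling (4 higher, 1 lower), −0.13 with quantile normalization, 0.02 without control sgRNA replicate 1, 0.07 without NMNAT1 sgRNA replicate 2 and 0.24 without control sgRNA replicate 2. Without NMNAT1 sgRNA replicate 1 it was 0.20, and 1 of its members was lower.

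More nuclear genes of oxidative phosphorylation were higher than lower, and the call of the list depended on the test and on the correction. Of 63 tested subunits, 42 were higher, 9 were lower and 12 did not pass. The median log2 fold change was 1.17 (interquartile range 0.14 to 1.96), with camera adjusted p = 0.00129. With an estimated correlation, where camera can hardly call a list from 2 libraries per group, its adjusted p was 0.714. ATP5PB, of the stalk of ATP synthase, rose from 0.949 ± 0.491 to 24.2 ± 4.41 FPKM. NDUFB3 of complex I was 9.41-fold higher, and COX7B of complex IV was 7.91-fold higher. The log2 fold changes of ATP5PB, NDUFB3 and COX7B were 3.70, 3.12 and 2.91, and 3.26, 1.71 and 2.20 when corrected. ATP5PB has 7 named pseudogenes and overlaps exons of WDR77, and NDUFB3 overlaps exons of FAM126B. The members' transcripts had a median GC content of 48.0% and a median length of 1179 bp. After correction for both, 34 members were higher and 17 lower, the median was 0.58 (interquartile range −0.45 to 1.10) and camera gave adjusted p = 0.296, as the list's median had moved toward the median of all tested genes, which was −0.15 before and 0.12 after. Among 21 tested glycolysis genes, 12 were lower, 5 were higher and 4 did not pass (median −0.76, camera adjusted p = 0.157). The glycolysis median was −0.18 when corrected, with 4 higher and 9 lower, and −0.18 with total-read scaling, with 7 higher and 8 lower; without NMNAT1 sgRNA replicate 1, 3 were higher. Without a filter camera called the glycolysis list lower (adjusted p = 0.0193, against 0.714 with an estimated correlation and the filter). ENO1 was 2.91-fold lower and the glucose transporter gene SLC2A1 4.23-fold lower, whereas LDHB was 14.9-fold higher. Cholesterol synthesis and uptake genes were split, with 6 higher, 6 lower and 4 not passing. EBP rose by 2.33 on the log2 scale, NSDHL went from 1.03 ± 0.401 to 10.4 ± 0.580 FPKM, and INSIG1, a sterol-sensing retention factor, fell by 2.35. LDHB, ENO1, PDIA3, PARP1 and PCNA also have named pseudogenes. The median of the cholesterol list was −0.34 and its mean 0.04 (camera adjusted p = 0.808), and its median was 0.22 with total-read scaling, 0.03 when corrected and −0.22 without NMNAT1 sgRNA replicate 1 or without control sgRNA replicate 2.

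Mitotic and DNA repair genes were more often higher than lower, although camera called neither list. Of 20 tested G2/M genes, 12 were higher, 4 were lower and 4 did not pass (median 1.46, camera adjusted p = 0.0732). When corrected, the G2/M median was 0.90 and the camera adjusted p 0.296. With total-read scaling 12 were higher and 0 lower (median 1.73), and with a pseudocount of 0.1 the median was 2.78. AURKB, the mitotic kinase of the chromosomal passenger complex, was 8.95-fold higher, the kinesin gene KIF2C rose from 0.377 ± 0.0904 to 13.1 ± 4.01 FPKM, and BUB3 rose by 2.60 on the log2 scale. Of 30 tested G1/S and replication genes, 16 were higher, 9 were lower and 5 did not pass (camera adjusted p = 0.296), but with at least 10 FPKM 5 were higher and 7 lower of 15 (median −0.44). PCNA, the replication clamp, was 9.81-fold higher, and MCM3 and CDC45 of the replicative helicase were 8.27-fold and 8.45-fold higher. The log2 fold change of PCNA was 2.94, and 1.93 when corrected. DNA repair had 15 genes higher, 4 lower and 3 not passing (median 1.24, camera adjusted p = 0.0732), with RPA3, XRCC5 and POLB up by 2.98, 2.15 and 1.93 (0.85 corrected for POLB). Of 14 tested replication-dependent histone genes, whose mRNAs mostly lack poly(A) tails, 7 were higher, 1 was lower and 6 did not pass. HIST1H1C, HIST1H2BJ and HIST1H4E were among the 7, and histone genes may share reads with near-identical copies. HIST1H2BJ had 1 read in each control library, against 23 and 25 in the others. The histone median was 1.02 (camera adjusted p = 0.148) and 0.14 when corrected, and 0.51 without NMNAT1 sgRNA replicate 2. Without NMNAT1 sgRNA replicate 1 or 2 the 4 lower G2/M genes became 2, and without replicate 1 the 4 lower repair genes became 2. When either control library was left out, camera called the G2/M list higher (adjusted p 0.0300 without control sgRNA replicate 1 and 0.0190 without control sgRNA replicate 2), and DNA repair without control sgRNA replicate 1 (adjusted p 0.0474). Without a filter camera called both lists higher (adjusted p 0.00186 and 0.0154), and at 5 CPM the G2/M list (0.0404). With an estimated correlation their adjusted p were 0.718 and 0.714.

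The list of immediate early and heat shock genes, which respond within minutes to growth signals or stress, had more members lower than higher, although camera did not call it. All 16 tested members of the immediate early and heat shock list, which was included as a sign of handling, changed, with 12 lower and 4 higher (median −1.49, camera adjusted p = 0.0732). IER2 fell from 282 ± 42.8 to 46.1 ± 2.11 FPKM, ZFP36, which promotes decay of AU-rich mRNAs, fell by 2.34 on the log2 scale, and the small heat shock protein gene HSPB1 fell by 2.28. The log2 fold changes of IER2, ZFP36 and HSPB1 were −1.65, −2.28 and −1.97 when corrected, and that of IER2 was −2.58 before. The 4 that rose, named after their values were seen, were HSPA8, HSPD1, HSP90AA1 and HSPE1, by 2.77, 1.94, 1.69 and 1.64. Corrected, 11 members were lower and 5 higher, with a median of −1.29 and camera adjusted p = 0.0776. Camera called the list lower without control sgRNA replicate 1 or 2 (adjusted p 0.0474 and 0.0190), with total-read scaling (0.0281) and without a filter (0.00110). With an estimated correlation it gave adjusted p = 0.714. Among 11 tested NF-kB and cytokine genes, 7 were lower, 2 were higher and 2 did not pass (camera adjusted p = 0.320), and the 7 became 3 or 4 without NMNAT1 sgRNA replicate 1 or 2. Corrected, 4 of them were lower and 2 higher, and the median went from −0.996 to −0.32; with total-read scaling 4 were lower and 3 higher (median −0.46). NFKBIA, the inhibitor induced by NF-kB, was 5.08-fold lower, whereas BCL2A1 rose by 2.73 and CXCL8, with 0.0386 and 0 FPKM in controls, by 2.57 on the log2 scale (1.24 and 1.03 corrected).

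Other stress and interferon lists held members of both directions. Of 26 tested ATF4 and integrated stress response genes, 13 were higher, 9 were lower and 4 did not pass (median 0.56, camera adjusted p = 0.496). With total-read scaling 15 were higher and 3 lower (median 1.09), and corrected 14 were higher and 5 lower (median 0.85). DDIT3 (CHOP) rose from 0.430 ± 0.292 to 8.49 ± 0.490 FPKM, whereas PPP1R15A (GADD34) fell from 113 ± 32.7 to 19.4 ± 1.02 FPKM. DDIT3, with 3 and 7 reads in controls and 144 and 147 in the others, overlaps exons of MARS, another member that was higher. The log2 fold change of DDIT3 was 2.74, and 1.80 when corrected. Of 20 tested genes of the unfolded protein response of the endoplasmic reticulum, 11 were lower, 5 were higher and 4 did not pass (camera adjusted p = 0.541). PDIA3 fell by 1.81 on the log2 scale, and SEC61B and HSP90B1 rose by 2.03 and 1.66 (0.72 and 1.11 corrected); with total-read scaling 8 were higher and 4 lower, and the list's median moved from −0.58 to 0.01. All 13 tested interferon-stimulated genes changed, 9 higher and 4 lower (camera adjusted p = 0.296), with IFI35 18.2-fold higher, IFITM2 4.77-fold higher and OASL up by 1.06 on the log2 scale. IFITM2 overlaps exons of IFITM1. In the BCL2 family and apoptosis list of 20 tested genes, 7 were higher, 8 were lower and 5 did not pass (camera adjusted p = 0.882). With total-read scaling 9 were higher and 3 lower, and without a filter 8 were higher and 3 lower of 33. CYCS, the gene of cytochrome c with 40 named pseudogenes, rose by 2.57 and the death receptor adaptor gene FADD fell from 195 ± 19.5 to 63.6 ± 1.85 FPKM. The median of that list was 0.09, and 0.48 with total-read scaling, 0.25 when corrected, −0.18 and −0.01 with quantile normalization and median centring, −0.02 without NMNAT1 sgRNA replicate 2, −0.18 without control sgRNA replicate 2, 0.02 without control sgRNA replicate 1 and 0.17 without NMNAT1 sgRNA replicate 1. Without NMNAT1 sgRNA replicate 1 or 2 the lower counts were 2 or 3 for that list, 5 for the ATF4 list, and 5 or 4 for the unfolded protein response, and without control sgRNA replicate 2 the lower count of the BCL2 list was 5.

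Most members of the leukemia program list past the filter were lower and several myeloid maturation genes rose, although camera called neither list with the authors' scaling and no correction. Of 27 listed and 9 tested MLL-fusion targets and leukemia stem cell genes, 8 were lower and 1, MYB, was higher (median −1.19, camera adjusted p = 0.0732, and adjusted p = 0.714 with an estimated correlation). HOXA7 was 10.6-fold lower, at 0.211 and 0.0954 FPKM against 1.58 and 1.67 FPKM. DOT1L, the H3K79 methyltransferase gene, fell by 1.28, but its transcript has 62.7% GC and its corrected log2 fold change was 0.13 (limma adjusted p = 0.559). MYB rose by 0.96. Without a filter, 5 of the 27 were lower and 4 higher (median −0.18). Corrected, 7 of the 9 were lower and 1 higher, with camera adjusted p = 0.0776, and 0.0466 when the correction had an interaction. With total-read scaling camera also called the list lower (adjusted p = 0.0384). With an estimated correlation the corrected fit gave adjusted p = 0.556. Of 27 tested monocyte and granulocyte genes, 13 were higher, 9 were lower and 5 did not pass (median 0.42, camera adjusted p = 0.594). The median was 0.18 without control sgRNA replicate 2, and −0.02 with at least 10 FPKM, where 7 were higher and 7 lower. With total-read scaling it was 1.00, with 16 higher and 6 lower. S100A9 and S100A8, the subunits of calprotectin, rose by 3.30 and 2.49 (2.53 and 1.27 corrected), and the myeloid surface receptor gene CD33 was 9.05-fold higher. The S100A8 values rest on 1 and 0 reads in control libraries, against 70 and 72 in the others.

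Ribosome biogenesis genes were mostly higher, and the direction of ribosomal protein genes depended on the scaling. Of 30 tested ribosome biogenesis genes, 17 were higher, 5 were lower and 8 did not pass (median 0.70, camera adjusted p = 0.0732). With total-read scaling the median was 1.09, and without a filter camera called the list higher (adjusted p = 0.0170, against 0.718 with an estimated correlation). Besides NPM1, POLR1C, a subunit shared by RNA polymerases I and III, was 12.4-fold higher and NOP16 was 6.86-fold higher. POLR1C overlaps exons of XPO5 and YIPF3, among others, and NOP16 those of ARL10 and HIGD2A. Reads of such overlaps are not separated here. Of 76 tested cytosolic ribosomal protein genes, 29 were higher, 18 were lower and 29 did not pass (median 0.05, camera adjusted p = 0.676). With total-read scaling 46 were higher and 7 lower (median 0.63), and with quantile normalization 39 were higher and 8 lower. RPS7 and RPL23, with 15 and 5 named pseudogenes, rose by 1.86 and 1.77 (1.03 and 1.31 corrected), and RPS19, with 4, fell from 9765 ± 312 to 3821 ± 148 FPKM. Corrected, 9 ribosomal protein genes were higher and 39 lower, the median was −0.40 and camera called the list lower (adjusted p = 0.00373, and 0.556 with an estimated correlation); with quantile normalization camera called it higher (adjusted p = 0.00695), and with median centring its median was −0.05. Without NMNAT1 sgRNA replicate 1 or 2, 18 ribosomal protein genes were higher, and the 5 lower biogenesis genes became 3 or 2. The ribosomal protein median was 0.07 to 0.14 without 1 library at a time, the highest without control sgRNA replicate 1. Adjusted over the list alone, the ribosomal protein counts were 25 higher and 17 lower, DNA repair had 5 lower in place of 4, and the counts of the other lists were as given.

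**Figure D3:**
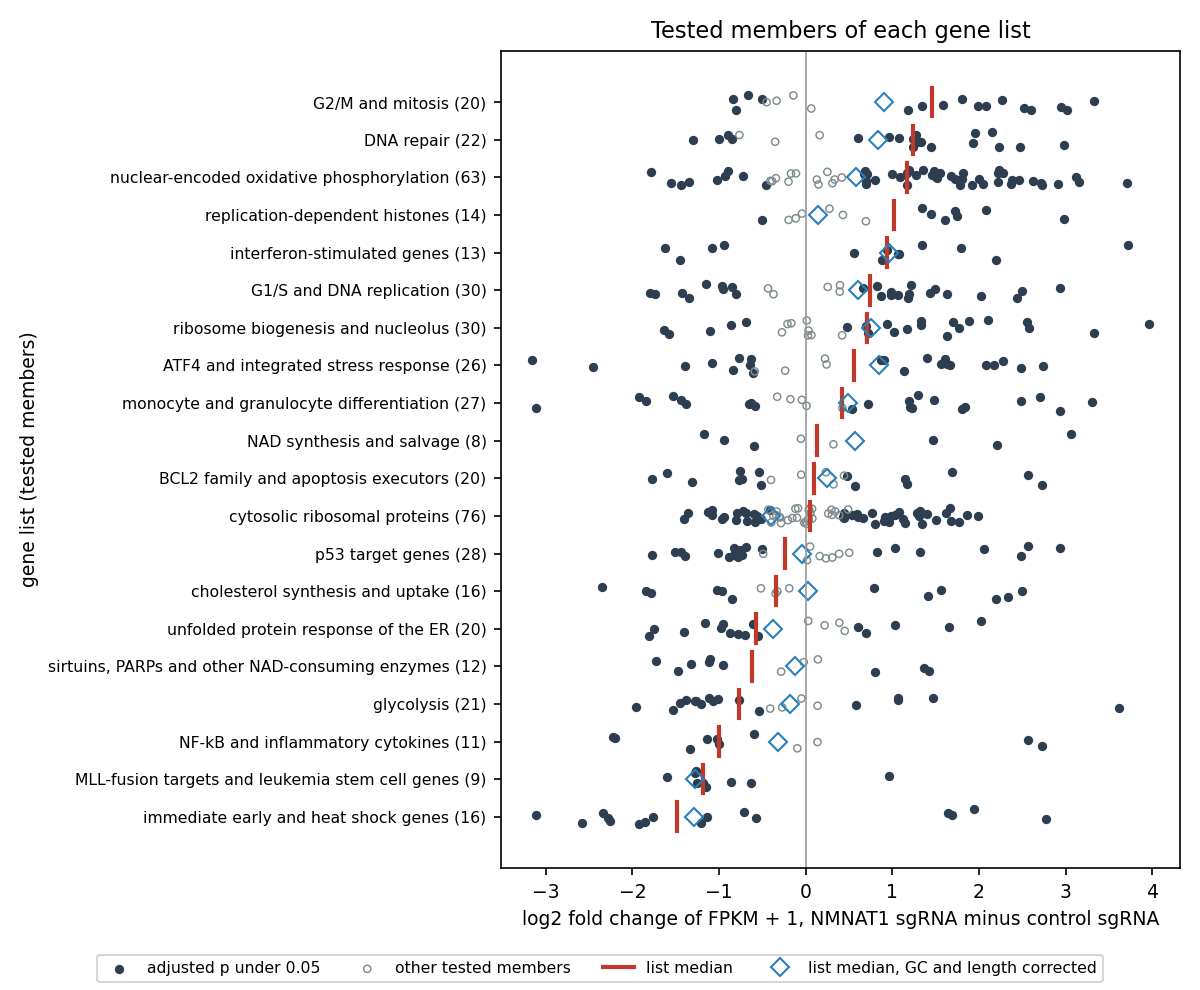
Log2 fold change of FPKM + 1 (horizontal axis, NMNAT1 sgRNA minus control sgRNA) of the tested members of 20 gene lists (vertical axis, number of tested members in parentheses), filled where adjusted p was under 0.05. Red bars mark list medians and blue diamonds the medians after GC and length correction; that of oxidative phosphorylation goes from 1.17 to 0.58 and that of the immediate early and heat shock genes from −1.49 to −1.29.

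Markers of other cell types were few. Of 22 lymphocyte markers, 3 were tested and all 3 were higher. NKG7, a granule membrane protein of cytotoxic lymphocytes, rose from 53.5 ± 6.62 to 249 ± 30.3 FPKM, CD3D rose from 0.498 ± 0.437 to 9.38 ± 2.24 FPKM and CD79B from 0.548 ± 0.0772 to 1.26 ± 0.0636 FPKM. The CD3D values rest on 2 and 7 reads in controls, against 141 and 111 in the others. The CD79B call was lost with quantile normalization (adjusted p = 0.601), limma-voom (0.0677) and no filter (0.0647). Among erythroid and megakaryocyte markers, HBD, listed at 0 in both control libraries, had 4.76 and 1.41 FPKM in the others. HBD rose by 1.90 on the log2 scale, and by 0.94 when corrected (limma adjusted p = 0.0472). When the correction had an interaction, neither HBD nor EPOR was called. EPOR fell by 0.78 (limma adjusted p = 0.0231), a call lost without either NMNAT1 sgRNA library or without control sgRNA replicate 2 (adjusted p 0.0858 to 0.238). The EPOR call was also lost when corrected (−0.36, adjusted p = 0.198) and with total-read scaling (log2 fold change −0.26). Of the epithelial, fibroblast and packaging-line markers 1 was tested, EPCAM, with a log2 fold change of −0.29 ± 0.20 (adjusted p = 0.193), which passed without NMNAT1 sgRNA replicate 2 (adjusted p = 0.0192), when corrected (−1.01, adjusted p = 0.00726) and with quantile normalization (−0.68, adjusted p = 0.0119). Without NMNAT1 sgRNA replicate 1 it was −0.03. Mitochondrially encoded mRNAs were not analysed here.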

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

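The GC and length corrections, quantile normalization, median centring, limma-voom and the minimum of 10 FPKM were chosen after seeing the data; the other alternatives were listed before. With total recovered reads as the scale, 1300 genes were lower and 12 p53 targets higher (2288 and 7 in the report). With at least 10 FPKM, which tests fewer genes, the counts were 887 higher, 1103 lower and 4 p53 targets higher, and a 2-fold minimum left 1296 lower. Without 1 library at a time, 1901 to 2143 genes were higher and 1409 to 2284 lower, the lowest count without NMNAT1 sgRNA replicate 1, and 6 to 8 p53 targets were higher. A library left alone in its group is assumed to vary like the other group. With the replicate number as a block, 2153 genes were higher and 2251 lower, and the deviations of replicates with the same number had a correlation of −1.65e-04 across genes.

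The NMNAT1 difference of 0.56 was 1.90 with a pseudocount of 0.1, which adds less to a low value, 0.37 with quantile normalization and 2.66 with limma-voom without a filter (adjusted p 0.0135), and 0.40 to 0.73 without 1 library at a time. It stayed positive in each alternative run, with limma adjusted p 0.0517 where only the filter was left out, and below 0.05 with the block (0.0369) and corrected (0.0316, and 0.0380 with an interaction).

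Of the gene lists, 1 was called higher and 0 lower in the report. With an estimated correlation camera rests on 2 residual degrees of freedom and can hardly call a list. The counts were 0 higher with an estimated correlation; 11 higher and 3 lower with fry, which does not compare a list with other genes; 4 higher and 2 lower without a filter; and 2 higher at 5 CPM. Total reads gave 2 lower, the correction 0 higher and 1 lower, its form with an interaction 0 higher and 2 lower, and quantile normalization 2 higher. Without 1 library at a time, 1 to 3 lists were higher and 0 to 1 lower; the counts of 2 or 3 higher and 1 lower came without control sgRNA replicate 1 or 2.

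Of 94 tested named genes, 89 kept their side of the threshold under the correction and were not called the other way. DOT1L went to 0.13 under it, BBC3 to 0.48, and to 0.45 with an interaction, and SIRT7, 1 of the 89 and at −0.02 in the report, to 0.51 under the correction and to 0.59 with an interaction (adjusted p 0.0473). Except where a construction is named, the cause was not tested. The count-based tests listed before, and their scaling factors, were not run because the table held FPKM. The authors' size factors were already in the values, and NMNAT1 gave no value at 5 CPM or 10 FPKM. With 2 to 57 reads per library for NMNAT1, depth limits what its values show.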

Other observations

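The 6 gene lists here, and all tests below except those on short-lived mRNAs, STAT5 output, ERK output and the genes nearest to NMNAT1, were chosen only after the result was seen. Genes of late neutrophil granules and secretion, which mark maturing granulocytes, were mostly higher in the libraries labelled NMNAT1 sgRNA. Of 10 tested, 8 were higher and 2 lower (median log2 fold change 2.43, camera adjusted p = 0.00472, and 0.226 with an estimated correlation). The antimicrobial protein genes CAMP and BPI rose by 2.08 and 2.09, and the receptor gene GPR84 by 3.60. Without the 30 largest changes per direction, some of which had prompted the list, 6 members had a corrected median of 1.28 and camera adjusted p = 0.208.

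Most tested targets of STAT5, which FLT3 with an internal tandem duplication activates, were lower. Of 12 tested, 9 were lower (median −1.63, camera adjusted p = 0.00472, and 0.226 with an estimated correlation), among them the feedback inhibitor gene CISH at −1.99 and the cyclin gene CCND3 at −2.05. Of 9 tested ERK response genes 7 were lower (median −1.13, adjusted p = 0.0214, and 0.226 with an estimated correlation), with the transcription factor gene MYC at −1.25 and the phosphatase gene DUSP6 at −1.22. Actin cytoskeleton and SRF target genes had 13 lower and 4 higher of 20 (median −1.24, adjusted p = 0.0252, and 0.226 with an estimated correlation), with ACTB at −2.18. Corrected, the actin list had a median of −0.52 and adjusted p = 0.0808. Without the 30 largest changes per direction, which had prompted the choice of lists, and without genes of the immediate early list, camera called none of these lists (adjusted p 0.0579 for STAT5, 0.124 for ERK and 0.124 for actin). Hypoxia response genes had 8 lower and 4 higher of 15 (median −0.72, adjusted p = 0.0910), with BNIP3 at −2.04. Camera called the hypoxia list lower when corrected (median −0.48, adjusted p = 0.0368, and 0.207 with an estimated correlation), but not without the largest changes (corrected adjusted p = 0.265). Other short-lived mRNAs had 5 lower and 1 higher of 10 (median −0.89, adjusted p = 0.189).

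Most tested genes differed between the groups. A trend with GC content and length, of the form fitted here, is argued against as the whole cause. After each library's trend was removed, 67.8% of 5707 tested genes passed. The rule for this was written after the data were examined. Of the 3870 that passed, 3251 had been called before the removal, 3154 in the same direction and 97 in the opposite direction. The removal also took out trends between replicates, so a lower spread may add calls. A trend of another form would remain. Separate handling of the groups cannot be told apart from the guide, because the labels hold 0 batch, date, lane or run fields. An effect of the NMNAT1 guide on the cells may explain the rest, and it stays open.

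Of 16 tested immediate early and heat shock genes 12 were lower, although camera did not call the list. In either form of the correction, 11 of the 16 were still called lower. For those members, a GC and length trend of the fitted form is argued against as the whole cause. The median went from −1.49 to −1.29, and 1718 of all 5707 tested genes were lower after the correction. Camera did not call the corrected list (adjusted p = 0.0776, and 0.0938 with an interaction). Another rule, which also asked for a camera call, was therefore not met, and both rules were written after the data were seen. Other short-lived mRNAs had a corrected median of −0.55, and −0.48 with an interaction, so a general loss of such mRNAs also stays open. Lower STAT5 or ERK output may contribute, with corrected medians of −0.999 and −0.92. Camera gave each corrected list an adjusted p of 0.00675 (0.207 with an estimated correlation), which met the range set before these results were seen. The largest changes had prompted the choice of lists, however. Without the largest changes and shared genes the corrected medians were −0.53 and −0.87, with camera adjusted p = 0.0953 each, which leaves both undecided.

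NMNAT1 RNA was higher in the libraries labelled NMNAT1 sgRNA, and its difference with a pseudocount of 0.1, 1.90, lay at percentile 71.5 of the 200 genes nearest in GC content, length and level, whose 5th to 95th percentiles were −1.31 and 2.93, so the trend met the range set before the result was seen. The correction, weighed only afterwards, left it at 0.48, and at 0.46 with an interaction, against 0.56, with adjusted p 0.0316 and 0.0380. With 2 to 57 reads per library the gene lies near the floor, so the trend cannot be told apart from other causes. Exchanged labels also stay open, as these values do not decide about them. Of the libraries labelled NMNAT1 sgRNA, 2 of 2 lay above both controls, but 67.5% of those genes were higher too. At percentile 71.5 the difference was short of the 95% of those genes that the rule for exchanged labels asked for. A Cas9 cut also need not lower an mRNA. No biological explanation was tested.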
